A study of Mus musculus with 2 samples.

How the data were processed

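Dental pulp of C57BL/6 mice at postnatal day 12 was dissociated with enzymes, and cells negative for propidium iodide, which stains dead cells, were sorted for 10x Chromium 3' single-cell libraries, per the labels' protocols. One library came from control mice and 1 from mice with an endothelial knockout of Vegfr2. How many animals each library pooled is not given in the sources used here. The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, not normalised, in a filtered matrix of 31053 genes for each library. Per the file headers, the control matrix was written by Cell Ranger 5.0.0 and the knockout matrix by Cell Ranger 6.0.1, whereas the submitters' processing notes name Cell Ranger 6.0.1 and the build mm10 for the series. The software version therefore differs between the genotypes. Groups were taken from the labels. The matrices held 6050 barcodes and 53196024 UMIs in all, and 0 columns were left unmatched to a sample.

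Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. The mitochondrial limit was exceeded by 1053 control barcodes (30.2%) and 811 knockout barcodes (31.6%). The gene limit was missed by 265 and 194 barcodes and the UMI limit by 255 and 244, and a barcode can fail several limits. Together the limits left 2329 and 1683 barcodes. Doublets were called in each library with Scrublet as built into scanpy, at an expected rate of 0.8% per 1000 cells, and 20 control and 4 knockout barcodes (24 of 4012, 0.598%) were removed. This is fewer than the expected rate, so undetected doublets remain. The 2309 control and 1679 knockout cells kept held 31457606 and 15074756 UMIs.

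Counts were scaled to 10000 per cell and log-transformed. Both libraries were clustered together without batch integration, on 2000 variable genes chosen with the library as batch key. Mitochondrial, ribosomal and haemoglobin genes, Xist and 4 Y-linked genes were left out of these. Clustering used 30 principal components, 15 neighbours and the Leiden algorithm at resolution 1. The tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9.

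Of 22 clusters, 19 were named by fixed marker genes, each name resting on at least 3 markers detected in at least 10% of cells. A cluster whose 10 leading genes by fold, among genes detected in at least 25% of its cells, held more markers of another class than of its own stayed unnamed. The 3 unnamed clusters had the markers of glia but a pulp gene among the leading genes (101 control and 54 knockout cells), the markers of macrophages but dendritic leading genes (147 and 174 cells), and the markers of dental follicle but pulp leading genes (122 and 22 cells). The name of the pulp mesenchyme-like cluster 5 rests on a tie, since its leading genes held 1 marker each of pulp mesenchyme (Vcan), cartilage (Col9a1) and ameloblasts (Ambn), with the cartilage genes Col9a3 and Cnmd beside them. A cluster needed Dspp in at least 10% of its cells to be called odontoblast-like, a limit set after the data were seen. Cluster 5 had Dspp in 9.95% of its cells.

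Within each class, UMIs were summed per library and scaled to the total UMIs of the class as CPM. Knockout over control ratios carry exact conditional 95% intervals for the ratio of 2 Poisson rates, and shares carry exact Clopper-Pearson intervals. The class sums were 5254606 and 1054388 UMIs in endothelial-like cells, 3512389 and 1304090 in mural-like, 5357832 and 2978924 in pulp mesenchyme-like, 4586990 and 3038047 in glia-like and 4915119 and 2412623 in macrophage or monocyte-like cells, control before knockout. A fold against a class at 0 UMIs is a bound set with a floor of 3 counts over the class. No test and no p-value was made, because cells are not replicates.

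A total of 31 gene lists was fixed: VEGF receptors and co-receptors, tip, Notch, arterial, venous, capillary, fenestration and caveolae, endothelial junction, vascular basement membrane, lymphatic, proliferation, hypoxia and glycolysis, oxidative phosphorylation, mineralisation, fibrillar matrix, angiogenic ligands, pulp subsets, pericyte, smooth muscle contractile, BMP and TGF-beta targets, Wnt targets, Hedgehog targets, YAP targets, interferon response, inflammation, unfolded protein response, apoptosis and p53, dissociation stress, sex-linked, glial myelin and macrophage states. The median log2 ratio was taken over members with at least 20 UMIs over both libraries in the class, for lists with at least 3 such members. Intervals of medians came from 1000 Poisson draws, and percentiles from 10000 random lists of the same size matched on mean expression. Genes were named by a fixed rule in classes with at least 50 cells in each library. It took genes with at least 30 UMIs over both libraries, seen in at least 10 cells of the library where they were higher, and with a CPM of at least 25% of that in any other class there. Mitochondrial, ribosomal and haemoglobin genes, Xist, 4 Y-linked genes and unnamed gene models were left out. Other X-linked genes, such as Tsix, were not left out. Genes were ranked by the bound of the interval nearest to 1, and the 12 highest and 12 lowest in endothelial-like and pulp mesenchyme-like cells and the 5 highest and 5 lowest in other classes are given, where the interval excludes 1 and the ratio is at least 1.5-fold, apart from some genes that are not reported here. List members, Kdr and Vegfa could also be named. The groups, filters, markers, members of the lists, naming rule for genes and the alternatives not listed below as added later were fixed before the data were examined.

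For shares of cells with a UMI, each cell was thinned to 2000 UMIs and shallower cells were left out. Cells were called Xist-positive with at least 2 Xist UMIs and Y-positive with at least 1 UMI of 4 Y-linked genes. In the control library 1693 cells were Xist-positive and 328 were Y-positive, and in the knockout library 806 and 447. Gene coordinates came from the GENCODE M21 annotation of GRCm38 (mm10), which held 30934 of the 31053 gene identifiers (99.6%). How the submitters' counting treated near-identical genes is not given in the sources used here, and such genes are given as uncertain.

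The intervals were tested on simulated data drawn from the class means, with known ratios. They held the true ratio for 96.3% of unchanged genes in endothelial-like cells (10920 genes run) and 96.2% in pulp mesenchyme-like cells (12128 genes run). For genes set 2-fold higher the interval excluded 1 in 86.0% of those in endothelial-like cells and 100% of those in pulp mesenchyme-like cells, and for genes set 2-fold lower in 72.0% and 84.0%.

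Alternatives were a looser cell filter (200 genes, 500 UMIs, 20% mitochondrial) and a stricter one (1000 genes, 2000 UMIs, 5%), doublets kept, Leiden resolutions of 0.5 and 2, 4000 variable genes, each library clustered on its own, cells classed by their own markers, and clustering without Kdr and the list members. Others were the mean of the cells' CPM, median-ratio scaling over genes with at least 50 UMIs, thinning, list members with at least 100 UMIs, and 2 or 5 proliferation UMIs. Median-ratio scaling moved the median gene of each class by less than 0.1 on the log2 scale. Those added after the data were seen were removal of the top 3% of doublet scores, unnamed clusters given their best class, Xist-positive and Y-positive cells alone, pulp without cluster 16, pulp without the cell richest in Amelx, and classes without the knockout cell richest in a gene. The clustering without Kdr and list members left out 151 genes. These were Kdr and the members of the tip, arterial, capillary, proliferation, mineralisation, hypoxia and glycolysis and fibrillar matrix lists. Genes of the other lists alone, such as Flt1, Plvap, Vwf, Selp and Cldn5, were not left out.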

Results

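Single-cell RNA-seq was collected from the dental pulp, the soft vascular and nerve-bearing tissue inside the tooth, of mice at postnatal day 12. The series holds 2 libraries, 1 from control mice and 1 from mice in which Vegfr2 was knocked out in endothelial cells. The deposited tables held 3487 barcodes and 35918862 UMIs for the control library, and 2563 barcodes and 17277162 UMIs for the knockout library. The median barcode carried 8584 UMIs from 2953 genes in the control library and 5595 UMIs from 2213 genes in the knockout library. The control over knockout ratio of these median UMIs was 1.53. After filtering, 2309 control cells and 1679 knockout cells were kept, with medians of 12198 and 8293 UMIs. Each genotype had 1 library, so no difference has a replicate check and no test was made. Intervals are exact 95% intervals and cover counting error only.

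The design asks how the pulp differs when endothelial cells lack VEGFR2, the main signalling receptor for vascular endothelial growth factor A. The receptor is encoded by Kdr, which the annotation of the mouse build GRCm38 (mm10) places on the minus strand of chromosome 5, from 75932827 to 75978458, as a protein-coding gene (ENSMUSG00000062960). In endothelial-like cells Kdr had 1054 CPM (UMIs scaled to the class total) in the control library and 650 CPM in the knockout library, a ratio of 0.616 with an interval of 0.568 to 0.667. These levels rest on 5539 and 685 UMIs, seen in 371 of 405 control cells and 117 of 141 knockout cells. One knockout cell held 13.9% of the Kdr UMIs, and the ratio without it was 0.544. Libraries of this kind read the 3' end of transcripts, so tags from a transcript that lost an upstream exon would still be counted, and the level of Kdr checks nothing about the deletion. Endothelial-like clusters were also found without Kdr and without the members of the tip, arterial, capillary and certain other lists. Flt1, Plvap, Vwf and Selp were not left out there. Among these clusters, Kdr differed little in the one led by Esm1 and Plvap, at 2081 against 2108 CPM with a ratio of 1.013 (interval 0.892 to 1.15). The knockout value of that cluster rests on 18 cells and 273 Kdr UMIs. The ratio was 0.900 in the cluster led by Vwf and Selp, and 0.323 (interval 0.256 to 0.402) in the arterial-like cluster led by Gja5 and Sox17. After each cell was thinned to 2000 UMIs, which left out 32 control and 33 knockout endothelial-like cells, 75.9% of control and 56.5% of knockout endothelial-like cells had a Kdr UMI (91.6% and 83.0% unthinned, at median depths of 9880 and 5961 UMIs). In glia-like cells, at median depths of 12216 and 8598 UMIs, the thinned shares were 0.862% and 0.645%. Over all kept cells Kdr was at 184 CPM in the control library and 51.0 CPM in the knockout library.

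The knockout library held a lower share of endothelial-like cells and higher shares of glia-like, macrophage or monocyte-like, dendritic-like and T or NK-like cells. The shares of a library add up to the whole, so a lower endothelial-like share by itself raises the shares of the other classes. The ratios of the other classes were not corrected for this. Endothelial-like cells, recognised by Pecam1, Cdh5, Emcn and other markers of the vessel lining, made up 17.5% of kept control cells (405 of 2309, interval 16.01 to 19.2%). They made up 8.40% of kept knockout cells (141 of 1679, interval 7.12 to 9.83%), which was 2.09-fold lower, with a share ratio of 0.479 (interval 0.392 to 0.581). Mural-like cells, the pericytes and smooth muscle cells that wrap vessels, made up 11.997% and 9.83%, a ratio of 0.819 with an interval of 0.671 to 0.997. Glia-like cells, which in peripheral tissue are largely Schwann cells, made up 15.2% and 19.9%, a ratio of 1.30 (interval 1.12 to 1.52).

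Macrophage or monocyte-like cells made up 14.5% of control cells and 17.4% of knockout cells, a ratio of 1.20 with an interval of 1.02 to 1.41. Among the smaller immune classes, dendritic-like cells had shares of 1.78% and 3.63% (ratio 2.05, interval 1.36 to 3.12). The T or NK-like class had 19 and 32 cells, a share ratio of 2.32 with an interval of 1.27 to 4.32. B-like cells and neutrophil-like cells had ratios of 1.38 and 1.41, with intervals that included 1. The pulp mesenchyme-like class, the fibroblast-like cells of the tissue, was close in share, at 19.5% of control cells and 20.5% of knockout cells (ratio 1.05, interval 0.909 to 1.21). Its clusters went opposite ways, with share ratios of 0.478 and 0.410 for clusters 5 and 7 and of 5.74 for cluster 16. Clusters left without a name held 16.02% of control cells and 14.9% of knockout cells. Among these, the cluster with dental follicle markers had a share ratio of 0.248, at median depths of 17545 and 1647.5 UMIs. The share ratio was 1.63 for the cluster with macrophage markers and 0.735 for that with glia markers.

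The sort on live cells and the dissociation set which cells enter such shares, and the libraries also differed in the sex of their cells. Among cells that could be assigned, 16.2% in the control library and 35.7% in the knockout library had UMIs of Y-linked genes. The endothelial ratio was 0.480 in Xist-positive cells and 0.440 in Y-positive cells, so it lay on the same side of 1 in both. The mural ratio was 0.575 in Xist-positive cells and 1.69 in Y-positive cells, and the pulp mesenchyme ratio was 1.39 and 0.895, so neither kept its side of 1. The macrophage or monocyte ratio was 0.958 in Xist-positive cells, and the pulp mesenchyme ratio was 0.399 under the stricter cell filter and 1.74 when each library was clustered on its own, where 139 of the 164 control cells of pulp cluster 5 but none of its 57 knockout cells were named cartilage.

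**Figure D1:**
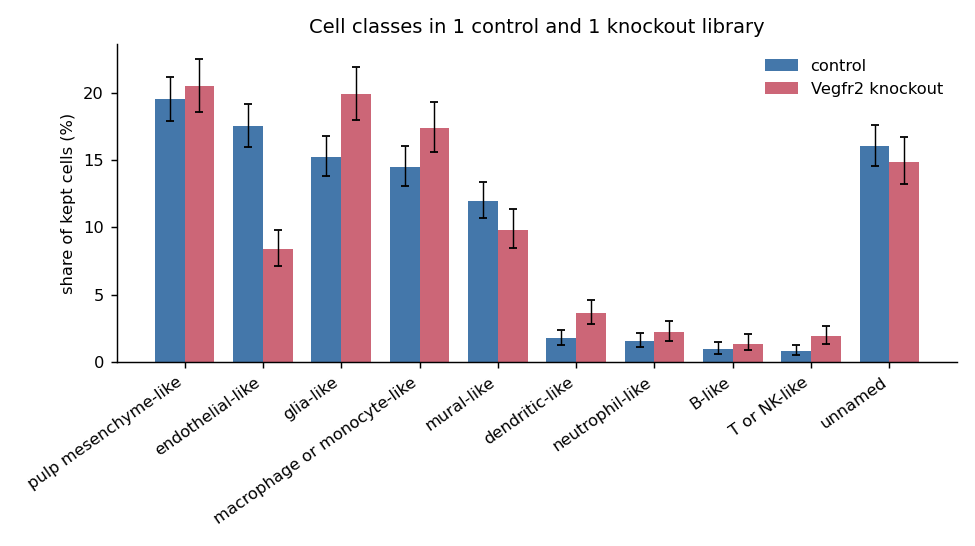
Share of kept cells, in percent, for each cell class in the control and knockout libraries (1 library each), with bars from 0 and error bars showing exact 95% intervals for counting error. Endothelial-like cells stood at 17.5% in the control library and 8.40% in the knockout library.

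No cluster met the criteria for odontoblast-like cells, the cells that lay down dentin. Dspp, which encodes the main non-collagen protein of dentin, had 74 UMIs in kept control cells and 3 UMIs in kept knockout cells. The limit on Dspp was set after the data were seen, and cluster 5 fell just below it, with Dspp in 9.95% of its cells. In that cluster Dspp was seen in 22 of 164 control cells and 0 of 57 knockout cells. The difference between the libraries itself therefore bears on this outcome. Naming under a lower limit was not tested, and under this limit the planned odontoblast comparisons have no value.

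Within the endothelial-like class, the knockout library held a smaller part of its cells in the cluster led by Esm1, Flt1 and Plvap, genes of sprouting and fenestrated capillary vessels. In the clustering made without Kdr and the list members left out with it, this cluster held 127 of 405 endothelial-like control cells (31.4%) and 18 of 141 knockout cells (12.8%), a ratio of 0.407 with an interval of 0.234 to 0.670. Flt1 and Plvap were not left out of that clustering. The ratio of the Esm1-led cluster was 0.154 (interval 0.0312 to 0.467) in Xist-positive cells and 0.333 (interval 0.0997 to 0.886) in Y-positive cells. These rest on 3 of 61 and 5 of 42 knockout cells. The arterial-like cluster led by Gja5 and Sox17 held 18.5% of the control cells and 28.4% of the knockout cells (ratio 1.53, interval 1.02 to 2.28). The cluster led by Vwf and Selp, genes of veins and activated endothelium, held most of the class in both libraries, with 50.1% and 58.9% (ratio 1.17, interval 0.899 to 1.52).

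**Figure D2:**
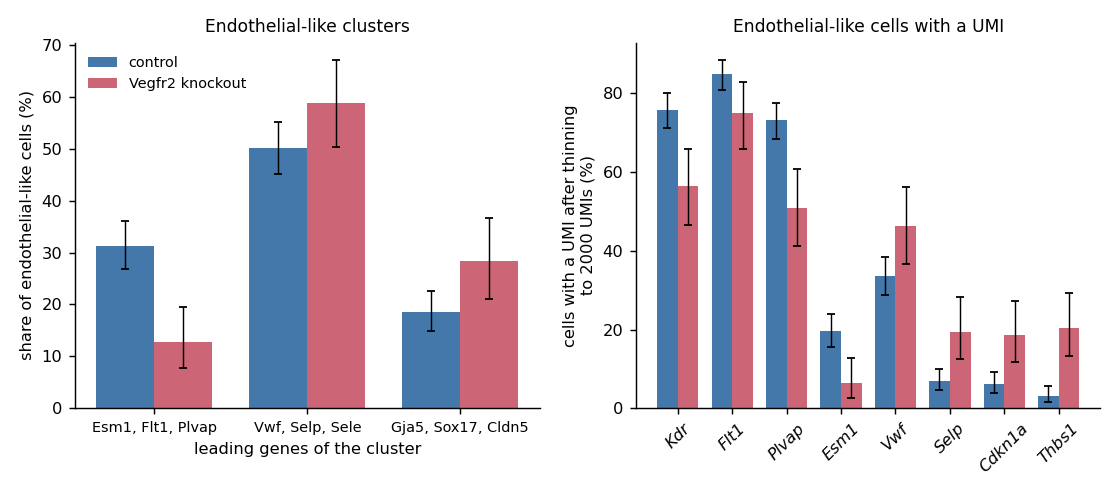
Share of endothelial-like cells, in percent, in each endothelial-like cluster of the clustering without Kdr and without members of the tip, arterial, capillary and certain other lists (left panel), and with a UMI of each of 8 genes after thinning to 2000 UMIs (right panel, 373 control and 108 knockout cells), as bars for the control and knockout libraries with exact 95% intervals. The cluster led by Esm1 holds 31.4% of control cells and 12.8% of knockout cells.

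Over the endothelial-like class as a whole, the knockout library had lower medians for receptors and tip cell genes and higher medians for arterial, venous and capillary genes, but the clusters of the class differed in share and most of these medians were not alike within them. The list of VEGF receptors and co-receptors had a median log2 ratio of −0.44 (interval −0.56 to −0.35), with 2 of 5 members at least 1.5-fold lower. Flt4, the receptor of lymphatic and sprouting endothelium, was at 65.8 CPM in the control library and 31.3 CPM in the knockout library, Flt1 was at 1628 and 1270 CPM, and Nrp1 was at 818 and 604 CPM. Tip cells lead vessel sprouts, and 4 of the 17 measured tip genes were at least 1.5-fold lower, 2 were at least 1.5-fold higher and 11 lay between, with 6 members above a ratio of 1 and a median of −0.30 (interval −0.47 to −0.13). Esm1, a secreted tip cell proteoglycan on the plus strand of chromosome 13 from 113209659 to 113218098, was at 284 CPM in the control library and 110 CPM in the knockout library, a ratio of 0.387 with an interval of 0.318 to 0.468. A single knockout cell held 48.3% of the Esm1 UMIs, the ratio without it was 0.205, and over all alternatives the ratio lay between 0.111 and 0.448. Kcne3 had a ratio of 0.172 and Nid2 of 0.533, while Plaur and Pgf had ratios of 2.49 and 2.15. The tip median lay at percentile 0.64 of 10000 random lists matched on expression, which describes its place in these libraries alone.

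The arterial list had a median of 0.71 (interval 0.54 to 0.90), with 7 of 12 members at least 1.5-fold higher and none as much lower. Fbln5, an elastic fibre protein, was at 115 CPM in the control library and 495 CPM in the knockout library, and the gap junction gene Gja5 at 44.5 and 70.2 CPM. The artery-specifying transcription factor Sox17 had a ratio of 1.70, whereas Efnb2 and Hey1 had ratios of 0.961 and 0.764. Among venous genes, 5 of 10 were at least 1.5-fold higher, with a median of 0.68. Selp, which encodes the leukocyte adhesion receptor P-selectin, had 68.1 CPM in control cells and 305 CPM in knockout cells, and the chemokine-binding receptor gene Ackr1 had 18.5 and 75.9 CPM. Of 10 measured capillary genes, 4 were at least 1.5-fold higher and none as much lower, with a median of 0.34 (interval 0.24 to 0.52) that was 0.12 when each cell counted equally. The fatty acid carrier genes Cd36 and Fabp4 had ratios of 6.35 and 2.62, and Gpihbp1, which anchors lipoprotein lipase, had a ratio of 0.688. These medians lay at percentiles 100, 99.99 and 97.6 of matched random lists.

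Within the clusters of the main clustering led by Esm1 (126 control and 14 knockout cells), Vwf (218 and 88 cells) and Cldn5 (61 and 39 cells), in that order, the arterial median was −0.17 (interval −0.58 to 0.17), 0.34 and −0.23 (interval −0.34 to −0.054), and the venous median was −0.074, 0.95 and −0.24. The median of the receptor list was −0.038, −0.16 and −0.45, that of tip genes −0.26, −0.059 and −0.82, and that of capillary genes 0.45, 0.49 and 0.51. In the clusters found without Kdr and the list members left out with it, led by Esm1, Vwf and Cldn5, the Flt1 ratio was 0.954, 1.06 and 0.783. Flt1 itself was not left out of that clustering. The higher arterial and venous medians of the class were thus seen within the Vwf-led cluster alone, and shares of clusters bear on the class values.

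Vessel wall genes went in more than one direction. The vascular basement membrane list had 11 of 13 members below a ratio of 1 and a median of −0.45 (interval −0.50 to −0.36), with Col15a1 at a ratio of 0.453, Col4a2 at 0.674 and Sparc at 1.30. Plvap, which forms the diaphragms of fenestrated capillaries, was at 957 CPM in the control library and 565 CPM in the knockout library, although the fenestration and caveolae list had a median of 0.053. The tight junction gene Cldn5 had 480 and 795 CPM while the endothelial junction list had a median of 0.075, and the Notch list had a median of 0.038. Lymphatic genes had 3 measured members and a median of −0.056.

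The difference of greatest size over a list was in proliferation. Of 30 measured cell cycle genes, 29 were at least 1.5-fold lower in knockout endothelial-like cells and none was higher, with a median of −2.28 (interval −2.55 to −1.89, or −2.19 with the 1 member at 0 set to its bound). The median was −1.50 in Xist-positive cells, −3.33 in Y-positive cells, −1.52 in cells thinned to 2000 UMIs and −0.21 when each cell counted equally. Within the clusters led by Esm1, Vwf and Cldn5 it was −0.0021, −2.22 and −1.54. Top2a, a topoisomerase of dividing cells, was at 137 CPM in the control library and 12.3 CPM in the knockout library, 11.1-fold lower (interval 6.44 to 20.9). Mki67 was at 124 and 20.9 CPM, and the tubulin gene Tubb5 had a ratio of 0.914. The share of thinned cells with 3 or more proliferation UMIs was 36.5% (136 of 373) in the control library and 39.8% (43 of 108) in the knockout library. That ratio of 1.09 (interval 0.756 to 1.55) goes against the CPM, the ratio over 20 thinning draws had a median of 0.848 with a range of 0.668 to 1.09, and no order is read from it. The unthinned shares were 86.7% and 74.5%, and the thinned ratio was 0.565 when at least 5 such UMIs were asked for. An Mki67 UMI was seen in 5.63% of thinned control and 1.85% of thinned knockout cells, and a Top2a UMI in 6.43% and 2.78%. These 2 shares lay on the side of the CPM, but rest on 2 and 3 knockout cells. The intervals of their ratios, 0.0374 to 1.35 and 0.0832 to 1.42, included 1.

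Of the genes ranked highest in knockout endothelial-like cells, 11 are given here, with ratios between 6.35 and 19.2, and 3 of them, Lox, Cdkn1a and Cd36, were members of the gene lists. The collagen and elastin crosslinking enzyme gene Lox had a ratio of 19.2 (interval 8.17 to 52.3), which was 3.45 in cells thinned to 2000 UMIs, and the secreted lipase inhibitor gene Angptl4 had a ratio of 11.7 (interval 7.06 to 19.98). Cdkn1a, which encodes the cell cycle inhibitor p21, was at 34.6 CPM in the control library and 255 CPM in the knockout library, with a ratio of 7.37 (interval 6.08 to 8.94). The bone morphogenetic protein genes Bmp4 and Bmp6 had ratios of 6.55 and 6.70, which were 17.3 and 12.3 in Y-positive cells, and 5 of 16 alternatives for Bmp4 lay outside its interval. Ratios for Lrrc32, Fgl2, Cd36, Cacna1e and Fam107a lay between 6.35 and 8.64, and that of Tiparp was 6.61, or 4.03 without the knockout cell that held 41.3% of its UMIs. The ratio of Cdkn1a was 2.85 in Y-positive cells and 13.4 in Xist-positive cells. Over the alternatives, the ratio of Cd36 lay between 3.30 and 28.2, that of Cacna1e between 4.58 and 32.7, that of Fam107a between 4.60 and 19.1 and that of Lrrc32 between 4.44 and 8.87.

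Of the 12 genes ranked lowest, 5 were members of the proliferation list, namely Top2a, Nusap1, Cenpf, Ccna2 and Tpx2. Nusap1 was 11.6-fold lower, Tpx2 was 9.27-fold lower and Cenpf was 7.83-fold lower. When each cell counted equally, the ratios of Top2a, Nusap1, Tpx2 and Cenpf were 0.443, 0.438, 0.678 and 0.913, against 0.0902, 0.0865, 0.108 and 0.128 from summed UMIs, so the size of these differences, and for Cenpf nearly the whole of it, depends on how cells are weighted. Ncapg and Ndc80 had no UMI in the knockout class, which makes them at least 6.55-fold and at least 5.35-fold lower with a floor of 3 counts over the class. Uhrf1 and Ckap2l had 1 UMI each in the knockout class, with ratios of 0.0297 (interval 0.000747 to 0.168) and 0.0412 (interval 0.00103 to 0.234). The ratios of Lockd, Rad51ap1 and Ccna2, on 1, 2 and 3 knockout UMIs, were 0.0361 (interval 0.000908 to 0.205), 0.0669 (interval 0.00803 to 0.246) and 0.0775 (interval 0.0158 to 0.230). The highest ratios over the alternatives were 0.0827 for Uhrf1, 0.197 for Ckap2l, 0.232 for Lockd, 0.288 for Rad51ap1 and 0.314 for Ccna2. The last, AY036118, was 4.48-fold lower and was also lower in the 11 other cell groups measured.

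**Figure D3:**
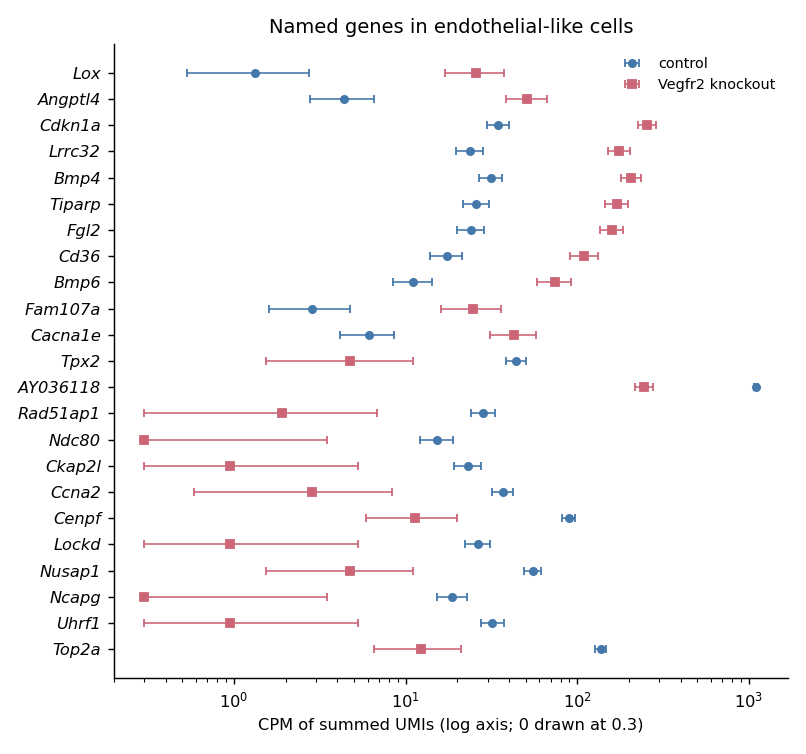
CPM of summed UMIs, on a log axis, in the control library (circles) and the knockout library (squares) for the genes given above as ranked highest and lowest in endothelial-like cells, with lines for exact Poisson 95% intervals and values below 0.3 CPM drawn at 0.3. Cdkn1a stands at 34.6 CPM in the control library and 255 CPM in the knockout library, and Top2a at 137 and 12.3 CPM.

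Hypoxia and glycolysis genes were higher in knockout endothelial-like cells in 24 of 29 members, with a median of 0.57 (interval 0.36 to 0.67). Bnip3, Egln3 and Vegfa, which respond to low oxygen, had ratios of 3.46, 3.797 and 1.86. Oxidative phosphorylation genes were lower in 17 of 18 members, with a median of −0.26. Inflammation genes (median 1.09, 8 of 9 at least 1.5-fold higher), interferon response genes (median 0.80) and fibrillar matrix genes (median 0.69) stood higher too, with ratios of 5.56 for Cxcl2, 3.69 for Ifit3 and 4.41 for Eln, the gene of elastin. In Y-positive cells the inflammation and interferon medians were 0.32 and 0.21. The dissociation stress list stood higher beside them, with all 16 members above a ratio of 1 and a median of 0.93 (interval 0.83 to 1.00), which was 1.32 in Xist-positive cells and 0.21 in Y-positive cells. Markers of other cell types also moved with these lists, since the pericyte list had a median of 1.37, the smooth muscle contractile list 0.96 and the macrophage states list 1.70 in endothelial-like cells, while glial myelin was at −0.35.

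The remaining lists gave medians of 0.38 for angiogenic ligands, 0.36 for BMP and TGF-beta targets, 0.13 for Wnt targets, 0.47 for YAP targets and 0.21 for apoptosis and p53 in endothelial-like cells. Thbs1, an inhibitor of vessel growth, had a ratio of 10.1 and Igf1 a ratio of 0.266 among the ligands. The unfolded protein response was at −0.0023, mineralisation at 0.56, pulp subsets at −0.44 and sex-linked genes at 0.88.

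**Figure D4:**
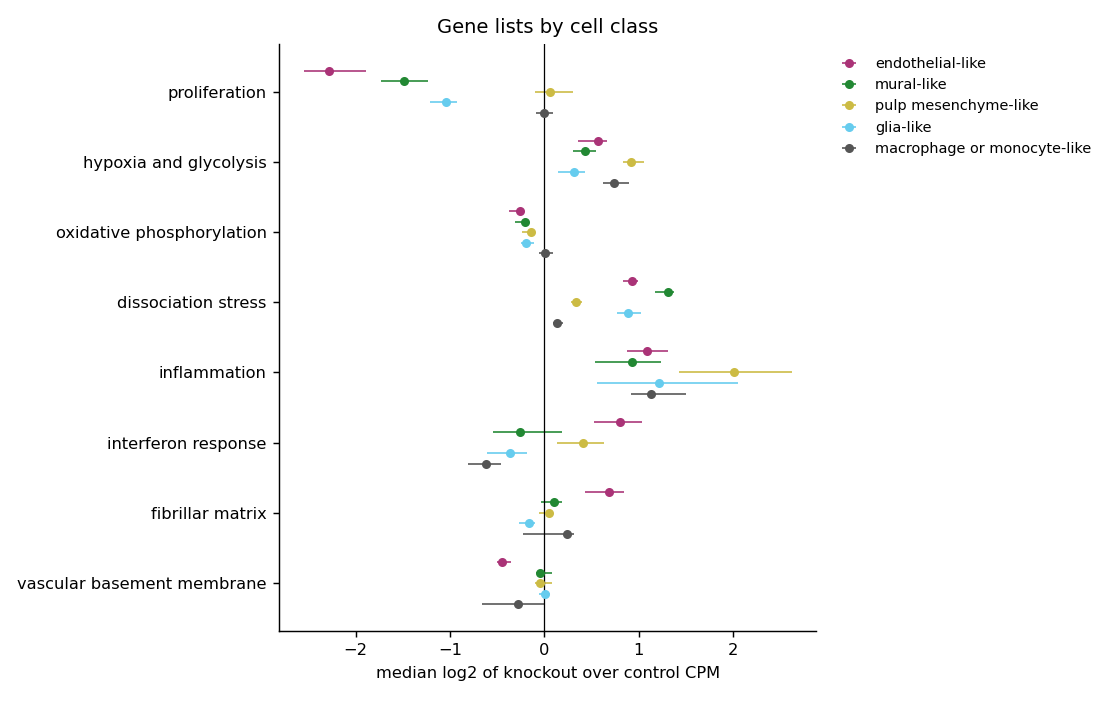
Median log2 ratio of knockout over control CPM over the measured members of 8 of the gene lists, one marker per cell class, with lines for 95% intervals from Poisson draws. Proliferation in endothelial-like cells stands at −2.28, and hypoxia and glycolysis in pulp mesenchyme-like cells stands at 0.92.

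In pulp mesenchyme-like cells the knockout library had higher levels of Vegfa and of nearly the whole hypoxia and glycolysis list. Vegfa encodes the ligand of VEGFR2 and lies on the minus strand of chromosome 17 from 46016993 to 46032369 as a protein-coding gene (ENSMUSG00000023951). It was at 88.3 CPM (473 UMIs) in the control library and 228 CPM (680 UMIs) in the knockout library, a ratio of 2.59 with an interval of 2.30 to 2.91. Of the 29 measured hypoxia and glycolysis genes, 22 were at least 1.5-fold higher, none was as much lower, and the median was 0.92 (interval 0.83 to 1.06, percentile 100 of matched random lists). The glycolytic enzyme genes Ldha, Tpi1 and Pfkl had ratios of 2.65, 2.68 and 2.67, the hypoxia-induced gene Ankrd37 had 12.3 and 73.2 CPM with a ratio of 5.94 (2.50 to 22.1 over the alternatives, 10 of 18 of them outside its interval), and Hk1 alone was lower, with a ratio of 0.777. The median was 0.97 in Xist-positive cells and 1.32 in Y-positive cells, and the Vegfa ratio was 5.02 under the stricter cell filter.

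Different clusters held most of this class in the 2 libraries, which bears on its values. Cluster 7 held 235 of the 451 control cells and cluster 16 held 217 of the 344 knockout cells, and 94.1% of the assigned knockout cells in cluster 16 were Xist-positive. Within clusters 5, 7 and 16 the hypoxia and glycolysis median was 1.02, 0.88 and 0.83, and the Vegfa ratio was 2.20, 1.67 and 1.49. The dissociation stress list had a median of 0.34 over the class, of 0.57 in Xist-positive and −0.52 in Y-positive cells, and of 0.16, −0.98 and −0.19 within these clusters.

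**Figure D5:**
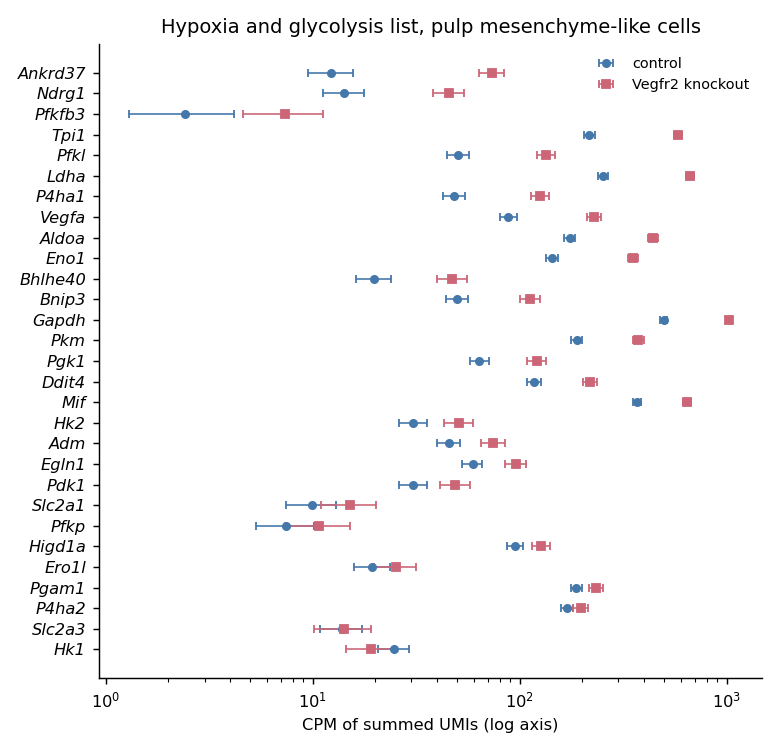
CPM of summed UMIs, on a log axis, in the control library (circles) and the knockout library (squares) for each measured hypoxia and glycolysis gene in pulp mesenchyme-like cells (451 control and 344 knockout cells), with lines for exact Poisson 95% intervals. Vegfa stands at 88.3 and 228 CPM, and Hk1 alone is lower in the knockout library.

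Matrix, mineralisation and cell cycle genes were on balance close between the libraries in pulp mesenchyme-like cells. The fibrillar matrix list had a median of 0.055 (interval −0.056 to 0.086), with 3 of 27 members at least 1.5-fold higher and 1 at least 1.5-fold lower. Col1a1 and Col3a1, the main collagens of pulp, had ratios of 0.935 and 1.06. The mineralisation list had a median of 0.030 (interval −0.10 to 0.092) over 19 members, 4 of them at least 1.5-fold higher and 4 at least 1.5-fold lower, with Slc20a1 at a ratio of 2.88 and Panx3 at 0.401. The proliferation list had a median of 0.061 (interval −0.099 to 0.31) over 20 members, which was −2.60 under the stricter cell filter. Pulp subset genes had a median of −0.016 and Hedgehog targets of −0.37. The unfolded protein response list had a median of −0.29, with 5 of 14 members at least 1.5-fold lower and 1 at least 1.5-fold higher, and ratios of 0.566 for the chaperone gene Pdia4 and 0.615 for Calr.

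Among the genes ranked highest in pulp mesenchyme-like cells, Gstp1 had a ratio of 14.5 (interval 10.3 to 20.9), but its sequence is shared with close paralogs and its value is uncertain in every class. Ppm1n, Gsto2, Pde4c and BC051537 had ratios of 14.9, 14.9, 14.4 and 13.5, and Lsmem1 had a ratio of 7.37. When cluster 16 was left out, the ratios of Pde4c, Lsmem1 and BC051537 were 1.10, 1.32 and 2.94 and Ppm1n had no knockout UMI, and in Y-positive cells the ratios of Gsto2 and Ppm1n were 2.68 and 0.358. Cd4, Duoxa1 and Iqch rested on 1, 1 and 2 control UMIs, with ratios of 63.0 (interval 10.6 to 2557), 57.5 (interval 9.61 to 2343) and 33.3 (interval 8.58 to 285). Amelx, the gene of the enamel protein amelogenin, had a ratio of 2734, and 1 knockout cell held 16678 of its UMIs, which were 46.3% of that cell's total. Without that cell the Amelx ratio was 7.12, with an interval of 3.61 to 15.3, and it was 7.48, 8.75, 11.5 and 9.90 in endothelial-like, mural-like, glia-like and macrophage or monocyte-like cells, so the rest of the difference was not particular to pulp mesenchyme-like cells.

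Among those ranked lowest, the gene of the small leucine-rich proteoglycan osteomodulin, Omd, was at 532 CPM in the control library and 150 CPM in the knockout library, 3.55-fold lower (interval 3.21 to 3.94). Over the alternatives the Omd ratio lay between 0.231 and 0.685, and Omd is a leading gene of cluster 5, which held 164 of the 451 control cells and 57 of the 344 knockout cells. The vesicle trafficking gene Rab3b was at 111 and 33.2 CPM, 3.35-fold lower. Slc12a1, Slc5a7, Snhg9, Khdrbs3, AY036118 and Tsix were 7.14-fold, 6.45-fold, 4.32-fold, 3.94-fold, 3.46-fold and 5.77-fold lower. The ratio of Slc5a7 was 0.546 when each library was clustered on its own, with 9 of 17 alternatives outside its interval, that of Snhg9 was 0.551 in thinned cells, and that of Rab3b was 0.537 in Y-positive cells. Those of Khdrbs3 and AY036118 reached 0.392 and 0.439 over the alternatives. Mia was 3.58-fold lower, yet its ratio was 1.13 to 4.62 under 7 of the clustering and filter alternatives and 8.05 in Y-positive cells. Dspp, Adamtsl3 and Gpc5 rested on 3, 2 and 3 knockout UMIs, with ratios of 0.0885 (interval 0.0178 to 0.271), 0.0922 (interval 0.0108 to 0.356) and 0.132 (interval 0.0261 to 0.413), and that of Gpc5 was 0.728 when each library was clustered on its own. Tsix lies antisense to Xist, so its level is uncertain. Xist-positive cells made up 73.3% of the control library and 48.0% of the knockout library, which may bear on the level of Tsix in every class. Over the alternatives the Tsix ratio in this class lay between 0.0663 and 0.214. It was at most 0.130 in mural-like and 0.290 in macrophage or monocyte-like cells. The alternatives included Xist-positive cells alone, so the share of such cells is argued against as the whole cause in these classes.

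Genes of other cell types also stood higher in this class. The glial myelin list had a median of 1.36 (0.38 in Y-positive cells) and the inflammation list a median of 2.02, with Il1b at 1.12 CPM in control cells and 6.71 CPM in knockout cells. The macrophage states, pericyte and capillary lists had medians of 0.84, 0.61 and 0.84, and that of the capillary list was −0.057 in Y-positive cells.

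Mural-like cells of the knockout library had lower medians for cell cycle genes and higher medians for dissociation stress genes and for genes of other cell types. The proliferation list had 26 of 30 members at least 1.5-fold lower and a median of −1.49 (interval −1.74 to −1.23), which was −3.35 in Xist-positive cells and −0.70 in Y-positive cells. The dissociation stress list had all 16 members at least 1.5-fold higher and a median of 1.31, with Fos at 412 CPM in the control library and 1251 CPM in the knockout library. Hypoxia and glycolysis genes had a median of 0.44, with 24 of 28 members above a ratio of 1. Pericyte genes were close, with a median of −0.12 and a ratio of 1.12 for Rgs5, and smooth muscle contractile genes had a median of 0.36, which was −0.085 in Y-positive cells. Among lists of other cell types, glial myelin had a median of 0.94 with all 6 measured members at least 1.5-fold higher, inflammation had a median of 0.93 and macrophage states a median of 0.57. The mineralisation list was lower, with a median of −0.48, which was −0.091 in Y-positive cells, and a ratio of 0.284 for the matrix protein gene Spp1. Angiogenic ligands had a median of 0.52, which was 0.16 in Y-positive cells, with ratios of 5.35 for Thbs1, 2.35 for Adamts1, 0.589 for Pgf and 0.350 for Igf1.

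Of the genes ranked highest in mural-like cells, Fst, which encodes the activin antagonist follistatin, was at 14.5 CPM in the control library and 205 CPM in the knockout library, a ratio of 14.1. One knockout cell held 47.2% of its UMIs, and the ratio without it was 7.52. Ccdc85b, Gstp1, Pappa2 and the nuclear receptor gene Nr4a3 had ratios of 12.8, 12.7, 8.55 and 7.04, and that of Pappa2 lay between 1.76 and 62.6 over the alternatives. Among the lowest, Tsix, Grp, AY036118 and the metallothionein gene Mt3 were 12.4-fold, 7.29-fold, 5.89-fold and 5.14-fold lower, and the histone gene Hist1h2be, which has near-identical copies, was at least 4.33-fold lower.

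Glia-like cells of the knockout library had a higher median for myelin genes and a lower one for cell cycle genes, while lists of another cell type moved further than the myelin list. All 10 measured myelin genes were above a ratio of 1, with a median of 0.55 (interval 0.53 to 0.59) and a ratio of 1.93 for the myelin basic protein gene Mbp. The macrophage states list had a median of 1.20 (0.53 in Y-positive cells) with 4 of 6 measured members at least 1.5-fold higher, and the inflammation list a median of 1.22. The proliferation list had a median of −1.04 (interval −1.21 to −0.92), with 22 of 30 members at least 1.5-fold lower, and was −0.25 in Xist-positive cells, −1.97 in Y-positive cells and −0.26 under the stricter cell filter. The dissociation stress list had a median of 0.89, with 190 and 697 CPM for Fos. Cluster 0 held 182 of the 352 control cells and cluster 15, led by myelin genes, held 185 of the 334 knockout cells. Beside Fos, the genes ranked highest were Gstp1, Ccdc85b, Mertk and Galnt16, with ratios of 17.5, 7.39, 4.08 and 3.73, and over the alternatives that of Mertk lay between 2.10 and 7.24 and that of Galnt16 between 2.81 and 8.46. The lowest were the histone genes Hist1h3c and Hist1h2af, whose near-identical copies make them uncertain, on 3 and 2 knockout UMIs with ratios of 0.0200 (interval 0.00408 to 0.0591) and 0.0419 (interval 0.00498 to 0.157), and Hist1h1b and the cyclin gene Ccne2, which were 13.8-fold and 10.1-fold lower. Mlf1 was at least 7.95-fold lower.

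Macrophage or monocyte-like cells of the knockout library had higher hypoxia and glycolysis and inflammation genes and lower interferon response genes. Hypoxia and glycolysis had 18 of 28 members at least 1.5-fold higher and a median of 0.74 (interval 0.62 to 0.90), with Vegfa at 7.12 CPM in the control library and 39.8 CPM in the knockout library and the glucose transporter gene Slc2a1 at 13.8 and 46.8 CPM. The inflammation list had 9 of 15 members at least 1.5-fold higher and a median of 1.13 (interval 0.92 to 1.51), with ratios of 6.08 for Ptgs2 and 2.998 for Il1b, but its median was −0.33 in Y-positive cells. Interferon response genes had 8 of 14 members at least 1.5-fold lower and a median of −0.62 (interval −0.81 to −0.45), with a ratio of 0.324 for Ifit3. The macrophage states list was split, with a median of −0.013, a ratio of 3.04 for the monocyte gene Ly6c2 and a ratio of 0.622 for the antigen presentation gene H2-Aa. The proliferation and dissociation stress lists had medians of −0.0043 and 0.14, which were 0.30 and 0.50 in Xist-positive cells and −1.04 and −0.63 in Y-positive cells, and the glial myelin list had a median of 0.46.

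Cluster 3, with antigen presentation genes among its leading genes, held 157 of the 335 control cells of the class, and cluster 13, led by the monocyte genes Lyz2 and Ly6c2, held 136 of the 292 knockout cells. The genes ranked highest in the class were Hist1h2ap and Gstp1, both uncertain for shared sequence, Prtn3 and Thbs1, with ratios of 14.6, 11.96, 10.6 and 6.15, and Lyz1, with a ratio of 10.0 that was 4.42 without the knockout cell holding 55.9% of its UMIs. The lowest were Ifi202b and Mmp13, at least 18.7-fold and at least 5.07-fold lower, and AY036118, Tsix and Cd209b, which were 7.14-fold, 6.17-fold and 4.54-fold lower. A single control cell held 45.2% of the 31 control UMIs of Mmp13. The ratio of Cd209b was 0.858 when each library was clustered on its own, with 7 of 16 alternatives outside its interval. Those of Hist1h2ap and Prtn3 were 5.72 and 4.04 there, that of Thbs1 was 2.61 in Y-positive cells and that of Lyz1 was 2.57 under the stricter cell filter.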

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

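The 2 comparisons of shared 3' sequence were written before their results, and the other tests here were chosen only after the result was seen, as was the 2-fold size used to pick genes that go opposite ways, which was lowered from 3-fold when no gene met that.

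The share ratio of mural-like cells was 0.575 in Xist-positive cells and 1.69 in Y-positive cells, opposite directions in the 2 sexes of cells. Fgl2 was 6.61-fold higher in endothelial-like cells of the knockout library and 2.22-fold lower in its macrophage or monocyte-like cells. Top2a was 11.1-fold lower in endothelial-like cells and 2.16-fold higher in pulp mesenchyme-like cells. Mt3 was 5.14-fold lower in mural-like cells and 2.82-fold higher in glia-like cells. Mt3 is a leading gene of glia-like cluster 15, whose share bears on the glia-like value. That cluster held 130 of the 352 control and 185 of the 334 knockout glia-like cells. In each case the difference was not tested.

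Endothelial-like cells had a share ratio of 0.479 in the knockout library. Loss of shallow endothelial cells by the filter is argued against by the looser filter, under which the ratio was 0.502 with an upper bound of 0.596. Animals of 1 sex in a pool are argued against by a ratio of 0.480 in Xist-positive cells and 0.440 in Y-positive cells. Whole vessels lost in dissociation or sorting would lower mural-like cells as well, which was so in Xist-positive cells (0.575) and not in Y-positive cells (1.69), so this stays open. Loss of VEGFR2 from endothelial cells may also lower the share, but with 1 library per genotype it cannot be told apart from any other difference between the libraries.

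The hypoxia and glycolysis list had a median of 0.92 in pulp mesenchyme-like cells of the knockout library. Shared 3' sequence is argued against as the whole cause by a median of 0.85 over members without it. The cluster held mostly by Xist-positive knockout cells is argued against by a median of 0.99 without cluster 16. Dissociation stress, as far as the stress list measures it, is argued against within the 3 pulp clusters, where the highest median of that list was 0.16. Over the whole class the median of the stress list was higher, as given above. The list speaks only for its own genes, so other differences in handling between the libraries stay open. Less supply from vessels in the knockout pulp may be a cause, a hypothesis that 1 library per genotype cannot tell apart from other differences between the animals.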

How the results depend on the processing

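Removal of the top 3% of doublet scores, naming of unnamed clusters, Xist-positive or Y-positive cells alone, pulp without cluster 16 or without the Amelx-rich cell, and classes without the knockout cell richest in a gene were chosen only after the result was seen. The members of all 31 lists were fixed before the data were examined, but which lists to follow in which class, outside the planned comparisons, was also chosen only after the result was seen.

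Over 108 results and 1778 alternative values, 1741 lay on the main value's side of no change and 37 on the other side. An alternative was called reversed only where the main value's interval excluded no change, which was so for 13 of the 37. Over all alternatives, 1418 lay within the main value's interval and 347 moved outside it without being reversed. Of 230 alternatives for the 14 main results, 171 lay within the interval and 26 crossed to the other side. Of these 26, 2 were reversed, for the mural and macrophage shares. The other 24 belong to 5 results whose interval includes no change, so that no direction is read from them: 9 of 19 for mineralisation, 5 of 19 for proliferation and 3 of 19 for fibrillar matrix in pulp, 4 of 13 for the pulp share and 3 of 15 for endothelial cycling. The endothelial share ratio lay between 0.440 and 0.596, the Kdr ratio between 0.459 and 0.637, the tip median between −0.57 and −0.22, the arterial median between 0.43 and 0.83, and the hypoxia and glycolysis median in pulp between 0.89 and 1.46. Most cells of cluster 5 were left unnamed under the looser filter, with doublets kept, at resolution 2, with 4000 variable genes and without Kdr and list members, so pulp values then rest mainly on the other pulp clusters. The part that stayed was unequal, with 41 of 164 control and 32 of 57 knockout cells at resolution 2 and 11 and 20 without Kdr and list members. At resolution 0.5, 140 of its 164 control cells and 40 of its 57 knockout cells were named cartilage. With each library clustered on its own, 139 of the control cells were named cartilage and all 57 knockout cells pulp mesenchyme, so pulp values there compare unlike sets of cells. For other values the cause was not tested. Esm1, set outside the main results after its alternatives were seen, had ratios between 0.111 and 0.448 over 17 alternatives, of which 5 lay outside its interval. The planned odontoblast share, mineralisation, hypoxia and Vegfa results have no value under any setting. Every clustering used the same limit on Dspp, and the classing of cells by their own markers did not include odontoblasts, so it could name none. Depth limits genes with few UMIs, since endothelial-like cells of the knockout library held 1054388 UMIs in all. No paired analysis was possible because each genotype has 1 library and its replicate number is only a name.

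The values below are share ratios (mural, pulp, macrophage, endothelial), ratios of genes (Vegfa and others) and log2 list medians in pulp mesenchyme-like cells unless another class is named. Under the looser filter, Vegfa was 2.09, fibrillar matrix 0.22 and Mia 2.75. Under the stricter filter, shares were 0.596 for endothelial, 0.399 for pulp and 1.497 for macrophage, Vegfa was 5.02, and medians were 1.46 for hypoxia, −2.60 for proliferation and −0.17 for mineralisation. With doublets kept, the pulp share was 1.33, Vegfa 2.21, fibrillar matrix 0.17 and Mia 3.59. At Leiden resolution 0.5, the pulp share was 1.34, the macrophage share 1.42, Vegfa 2.09, fibrillar matrix 0.18 and Mia 3.39. At resolution 2, the pulp share was 1.35, Vegfa 2.13, fibrillar matrix 0.15 and Mia 1.78. With 4000 variable genes, the pulp share was 1.29, Vegfa 2.21, fibrillar matrix 0.20 and Mia 3.03. With each library clustered on its own, the pulp share was 1.74, the macrophage share 1.71, Vegfa 2.05, fibrillar matrix 0.21 and Mia 1.13. Without Kdr and list members, the pulp share was 1.44, Vegfa 2.14, fibrillar matrix 0.19 and Mia 4.62. With cells classed by their own markers, proliferation was −2.03 and mineralisation −0.27. Thinning gave 0.48 for arterial genes in endothelial-like cells, 0.088 for fibrillar matrix and 0.15 for mineralisation. The mean of cells' CPM gave 0.12 for capillary genes in endothelial-like cells and 0.10 for fibrillar matrix, and median-ratio scaling gave 0.11 for the latter. The endothelial cycling ratio was 0.565 with 5 or more proliferation UMIs.

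Among the alternatives chosen later, removal of the top doublet scores gave a macrophage share of 1.42. With unnamed clusters given their best class, the pulp share was 0.878, Vegfa 3.18, fibrillar matrix −0.072 and proliferation −2.44. In Xist-positive cells, shares were 0.575 for mural, 1.39 for pulp and 0.958 for macrophage, Kdr in endothelial-like cells was 0.480, and medians there were −0.49 for tip and 0.43 for arterial genes. In Y-positive cells, shares were 1.69 for mural and 0.895 for pulp, and ratios were 2.28 for Vegfa, 0.358 for Ppm1n and 8.05 for Mia. There the medians were 1.32 for hypoxia and 0.10 for fibrillar matrix, −0.57 for tip and 0.57 for capillary genes in endothelial-like cells, and −0.33 for inflammation in macrophages, and Kdr was 0.459. Without cluster 16, Vegfa was 1.83 and Ppm1n was at 0. Without the knockout cell richest in it, Kdr in endothelial-like cells was 0.544.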

Other observations

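The comparison of shared 3' sequence was written before its result, and the other tests here, with the genes and lists named, were chosen only after the result was seen, and the test of free RNA was split in 2 once its value over all 12 genes was known, and later widened to sources among the 5 classes.

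Vegfa was higher outside the pulp mesenchyme-like class too. It was at 10.9 CPM in the control library and 67.0 CPM in the knockout library in the unnamed cluster with macrophage markers and dendritic leading genes, a ratio of 6.16, and Pgf, another ligand of this family, had a ratio of 7.24 in macrophage or monocyte-like cells. Over all kept cells Vegfa was at 28.8 and 74.6 CPM. In mural-like cells, genes of Notch signalling stood on the higher side, with a median of 0.29 that was −0.30 in Y-positive cells, a ratio of 1.54 for the pericyte receptor gene Notch3 and a ratio of 1.71 for Nrarp. The YAP target Amotl2 had a ratio of 2.22 there, while pulp subset genes had a median of −1.07, with 110 and 46.8 CPM for Fabp7, but a median of 0.059 in Y-positive cells. Eln, the gene of elastin, had ratios of 5.30 in mural-like, 4.41 in endothelial-like and 2.95 in pulp mesenchyme-like cells.

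Calr, the gene of a chaperone of the endoplasmic reticulum, had ratios of 0.769 in endothelial-like, 0.659 in mural-like, 0.615 in pulp mesenchyme-like, 0.624 in glia-like and 0.559 in macrophage or monocyte-like cells. The unfolded protein response list had medians of −0.36 in glia-like, −0.20 in mural-like and −0.17 in macrophage or monocyte-like cells, with 2 of 14 members at least 1.5-fold lower in each, and of −0.0023 in endothelial-like cells. In Y-positive cells the medians were −0.49, 0.025 and 0.32 in the first 3 of these classes, so only that of glia-like cells kept its side of 0. Ddit3, a gene of the stress arm of this response, had a ratio of 2.17 in pulp mesenchyme-like cells. Interferon response genes were lower in glia-like cells, with a median of −0.37, and higher in endothelial-like cells, at 0.80, and these differences were not tested. In macrophage or monocyte-like cells Fn1 and Vcan had ratios of 3.09 and 5.74.

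Of 6774 genes with at least 50 UMIs over both libraries in each of the 5 classes, 12 were at least 2-fold apart in the same direction in each, 8 higher (Thbs1, S100a8, S100a9, Eno1, Gm10076, Erh, Ccdc85b and Neat1) and 4 lower (Tsix, Rps27rt, AY036118 and mt-Atp8). Gstp1, with ratios from 11.96 to 21.2 in the 5 classes, fell below this limit, with 42 UMIs in endothelial-like cells. Shared sequence may account for part of them, since 41.7% of the 12 had 3' sequence or exons in common with another gene, against 3.53% of 1106 genes matched on expression. Free RNA of neutrophils may account for S100a8 and S100a9, whose neutrophil level was at least 40.3 times that in any of the 5 classes of the knockout library, and stays open for the other 10. Of these, Thbs1 in 4 of the 5 classes and Neat1 in 2 had at least 10 times their level in another class of the same library, and the rest at most 7.68 times. The different Cell Ranger versions of the 2 libraries cannot be told apart from the genotype, with 1 library per version. No biological explanation was tested for these genes.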
